A study of Homo sapiens with 4 samples.

How the data were processed

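Total RNA of MCF-7 clones was labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample, per the labels' protocols. Groups and replicate numbers were taken from the sample titles: 2 arrays with empty vector and 2 with BP1. The authors deposited 1 table of linear intensity values per probe set and array. RMA, a method of background correction, normalization and summarization, is the tool named in the submitters' processing notes; its version and settings, and any further step, are not given in the sources used here. The deposited intensity values did not have the form that RMA usually leaves. They were on a linear scale, their lowest value was exactly 1 on every array, and their medians were 7.25 and 8.82 on the vector arrays and 14.1 and 11.4 on the BP1 arrays. The share of probe sets at the lowest value was 17.3%, 16.2%, 8.3% and 11.5% in the same order. No detection calls were used here. Log2 values of the deposited table had a median shift between groups of 0.52, BP1 minus vector, over all probe sets.

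The plan made before the data were examined assumed normalized log2 values. Since the values were neither, log2 intensities of the 8746 probe sets left after removal of 47 control probe sets were quantile normalized across the 4 arrays, which had been planned as an alternative. A common floor of 0.42 log2 units was then set, the normalized level below which at least 1 array held only values at its deposited minimum. Values within 0.01 of it count as at the floor, a tolerance set after the values were seen. Where both arrays of a group were at the floor, the difference of the means is a lower bound and is given as "at least". That wording concerns the floor only and does not cover the spread between the arrays of the other group. Where 1 array of the group with the lower mean was at the floor, the printed difference is a lower bound of its size too. The fit on unnormalized log2 values, as first planned, was kept as an alternative. All levels and differences reported depend on this normalization, which removes any overall difference in signal between arrays. Absolute changes common to most genes can therefore not be seen.

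Differences were tested per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without intensity trend, two-sided, Benjamini-Hochberg adjustment over all 8746 probe sets, threshold 0.05), with no block and no filter on dim probe sets. The prior degrees of freedom were 1.03. Adjusted p-values in the text without another name come from this test for genes and from camera for lists. Gene names came from the platform annotation, updated through gene identifiers to the RefSeq table of assembly GRCh38.p14: 7840 probe sets had 1 gene symbol, 388 several and 518 none, and only the first kind was named. No coordinates are printed, since the build behind the probe sets is not given in the sources used here. For each gene the probe set with the highest mean over all arrays was used.

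The 29 gene lists held 876 genes, 708 of which were measured, and were fixed before the data were examined. They were tested with camera (inter-gene correlation 0.01, Benjamini-Hochberg over the lists), and with an estimated correlation and with fry as alternatives. Shifts of a list are relative to the mean, or for medians the median, of all genes. Genes were named by a rule fixed at the same time: DLX4; 7 genes tied to BP1 in earlier work; in each direction 12 genes past the threshold with the largest difference or, as happened here, the 12 with the smallest unadjusted p among genes whose arrays stood apart with at least a 1.5-fold difference; and up to 4 members of each list with the smallest unadjusted p. Bright genes (mean log2 level of at least 6) were ranked by size after the values were seen.

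The alternatives were arrays centred on their medians, filters on dim probe sets, an intensity trend, robust eBayes, the replicate number as a block, leaving out each array in turn, other thresholds, 1 value per gene and other list tests. Chosen after seeing the data were no normalization, no common floor, a crossed replicate block, and the filter with the trend. The computations were tested on simulated data for the comparison of BP1 with vector (8746 probe sets, 200 bright ones changed per run, 5 runs). With a spread of 0.1 all changed probe sets were called. With the spread of these arrays, mean estimates of changes of 1, 2 and 3 log2 units were 0.992, 2.01 and 3.03, and 4.13% of unchanged bright probe sets had an unadjusted p under 0.05. Camera called 100 of 100 simulated lists of 30 genes shifted by 1 log2 unit and 4 of 100 unshifted ones, at an unadjusted p under 0.05. Simulated genes varied independently, whereas the estimated correlation within the lists tested here reached 0.671, for the genes tied to BP1. The simulated shift also exceeded every mean shift seen here, so these shares may not carry over.

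The replicates were not copies of one another: among bright probe sets the SD of the log2 difference between replicates was 0.65 for vector and 0.49 for BP1. Figures were drawn with matplotlib 3.10.9.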

Results

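Gene expression was measured on 4 arrays of MCF-7 cells, an estrogen receptor-positive line of human breast cancer cells. The 2 vector arrays held total RNA of cells transfected with the empty expression plasmid pcDNA3.2. The 2 BP1 arrays held total RNA of cells transfected with the same plasmid carrying BP1, a homeodomain transcription factor encoded by DLX4. Per the series description, the replicates of each group were separate transfected clones (O1 and O4 for BP1, V1 and V2 for the vector), so the spread within a group, which the p-values measure, includes differences between clones. The question that the design poses is which transcripts differ when BP1 is overexpressed. The Affymetrix array carried 8793 probe sets, of which 8746 remained after 47 control probe sets were set aside. They named 7713 genes. Levels are given as log2 intensity after quantile normalization, and differences as BP1 minus vector on that scale, with the SE of the limma fit. The number of arrays limits the precision: the median SE of a difference was 0.3 among the 1390 probe sets with a mean level of at least 6, called bright here, and 0.54 among the others.

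DLX4, the gene that encodes BP1, was not separated between the groups. Its single probe set averaged 3.24 ± 0.43 (SD, n = 2) on the vector arrays and 3.21 ± 1.68 (SD, n = 2) on the arrays labelled BP1, a difference of -0.03 with a 95% interval from -3.24 to 3.18 and an adjusted p of 1. The array labelled BP1 replicate 1 held the highest value, 4.39, and the array labelled BP1 replicate 2 the lowest, 2.02, with the vector arrays between them at 2.93 and 3.54. Without BP1 replicate 2 the difference was 1.16. The deposited intensities ran the same way, from 4.55 on BP1 replicate 2 over 5.62 and 10.3 on the vector arrays to 27.2 on BP1 replicate 1. The position of this probe set within the transcript is not given in the sources used here, and a plasmid that carries only a coding sequence would not be read by a probe in the untranslated end, so the value may check nothing about the transgene. The DLX4 values go against the label of 1 of the 2 BP1 arrays, and every direction below is that of the arrays as labelled.

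Of 7 genes tied to BP1 in earlier studies, VEGFA, the main vascular endothelial growth factor, was the one whose arrays stood apart by at least 1.5-fold. It averaged 5.46 ± 0.28 on the vector arrays and 3.99 ± 0.03 on the arrays labelled BP1 (SD, n = 2 each), 2.76-fold lower, with a difference of -1.47 (SE 0.24, 95% interval from -2.24 to -0.69). Its adjusted p of 0.406 did not pass. BCL2, an inhibitor of apoptosis, differed by 0.00 (95% interval from -3.11 to 3.12), and BRCA1, a DNA repair gene, by -0.46 (95% interval from -2.64 to 1.72). ESR1, which encodes estrogen receptor alpha, differed by -0.19 (95% interval from -1.70 to 1.33). Its targets TFF1 and PGR both differed by -0.44, TFF1 at a level of 12.3 on the vector arrays and PGR near 2.47. Without 1 array TFF1 ranged from -0.60 to -0.27 and PGR from -0.81 to -0.06. HBB, the beta-globin gene at which BP1 was first studied, differed by -2.04 with a 95% interval from -7.31 to 3.23, and its value on BP1 replicate 1 lay at the floor of the scale. Without BP1 replicate 1 it differed by -0.39 and without BP1 replicate 2 by -3.69. None of the 7 passed over all genes or adjusted over the list alone, where the smallest adjusted p was 0.0635. Leaving out 1 array turned the direction of BRCA1 (0.23 without BP1 replicate 1) and ESR1 (0.33 without vector replicate 1), and BCL2 ranged from -1.11 to 1.12, so no direction is given for these 3 genes.

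**Figure D1:**
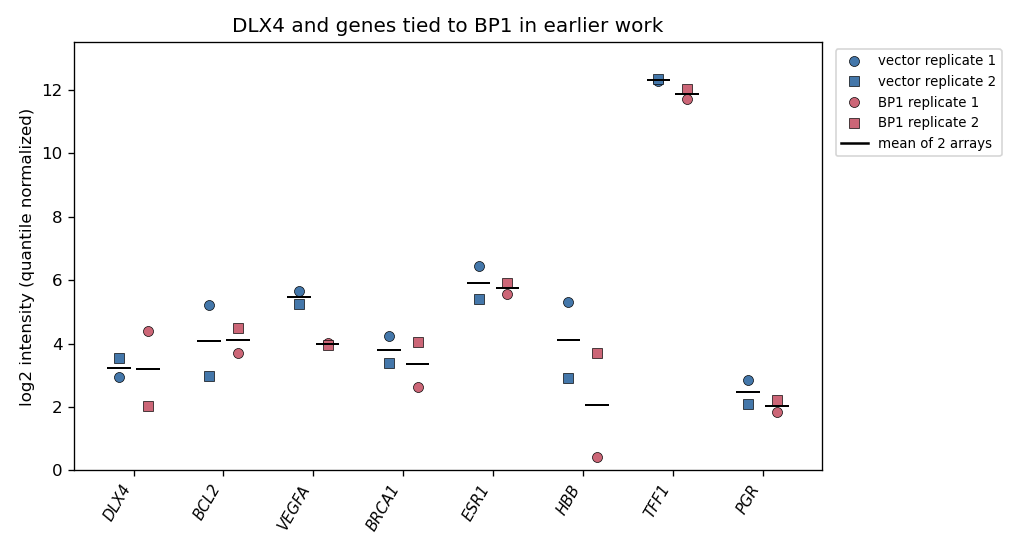
Log2 intensity after quantile normalization (vertical axis) of DLX4 and 7 genes tied to BP1 in earlier work, for each of the 4 arrays (circles for replicate 1, squares for replicate 2; blue for vector, red for arrays labelled BP1), with lines at the mean of 2 arrays. VEGFA lies at 5.65 and 5.26 on the vector arrays and at 4.01 and 3.97 on the BP1 arrays, whereas the BP1 arrays of DLX4 lie above and below both vector arrays.

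No probe set passed the threshold across the array. In limma's moderated test with Benjamini-Hochberg adjustment the smallest adjusted p among 8746 probe sets was 0.293, and the count at an adjusted p under 0.05 was 0. At an unadjusted p under 0.05 there were 667 probe sets, 340 higher and 327 lower on the arrays labelled BP1, where chance would give 437.3. The balance of directions depended on the scaling: 801 were higher and 133 lower without normalization, and 225 and 295 with median centring. At an unadjusted p under 0.01 there were 200 against 87.46 by chance. Setting vector replicate 2 and BP1 replicate 1 against the other arrays gave 205. With the replicate number as a block the count was 31, and with the crossed replicate block 61, both under the chance value. Both BP1 arrays lay on one side of both vector arrays in 31.8% of probe sets. Without ties chance gives 33.3% for 2 against 2. Arrays tied at the floor cannot stand apart, so the chance share over all probe sets is lower. Among the bright probe sets the share was 38.1%, or 530 of 1390. The arrays stood apart with at least a 2-fold difference in 1253 probe sets, 618 higher and 635 lower. On simulated arrays with the spread of these, the same test called 0% of bright probe sets changed by 1, 2 or 3 log2 units, although it gave 67.2%, 89.9% and 96.8% of them an unadjusted p under 0.05. The absence of calls in this fit therefore sets no upper limit on the changes of single genes. A fit of the bright probe sets with an intensity trend was chosen after seeing the data. It called 77.4% and 89.2% of the simulated changes of 2 and 3 log2 units, with 200 bright probe sets changed per run. On the arrays it called 0 of 1390 probe sets (smallest adjusted p 0.235). With fewer genes changed the share called can be lower, so the 0 calls do not show that large changes are absent. The genes named below are given as values, and leaving out 1 array moved 42 of 147 genes examined this way by over 1.5 times.

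Among the genes with the smallest unadjusted p, most of those higher on the arrays labelled BP1 were at or near the floor of the scale (0.42) on both vector arrays. Since arrays set to the floor have no spread between them, a ranking by p favours such genes in either direction. TEX14, a gene of intercellular bridges in germ cells, was at the floor on both vector arrays and averaged 4.61 ± 0.13 (SD, n = 2) on the BP1 arrays, at least 18.2-fold higher. SLC7A9, an amino acid transporter subunit, was at least 9.72-fold higher, FUT2, a fucosyltransferase, at least 6.82-fold, and KCNMB3, a potassium channel subunit, at least 6.40-fold. SHOX2, a homeobox gene, CALCRL, a peptide hormone receptor, and AURKC, an aurora kinase, were at least 5.40-fold, 5.19-fold and 5.27-fold higher. GDAP1, a mitochondrial outer membrane protein, was measured in both groups and went from 2.20 ± 0.25 to 5.85 ± 0.25 (SD, n = 2 each), a difference of 3.65 (SE 0.27). IGSF1, an immunoglobulin superfamily member, went from 3.29 ± 0.09 to 5.70 ± 0.09 (SD, n = 2 each). STAT5B, a transcription factor of cytokine and prolactin signalling, ZNF134, a zinc finger gene, and GPR176, an orphan receptor, differed by 3.16, 3.41 and 2.78, of which the first and second are lower bounds, since 1 vector array of each was at the floor. The adjusted p of each of these 12 genes was 0.293.

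Of the 12 genes with the smallest unadjusted p in the other direction, 7 were at the floor on both arrays labelled BP1. PDZK1, a scaffold protein that estrogen induces in breast cells, averaged 4.95 ± 0.49 (SD, n = 2) on the vector arrays and was at the floor on both BP1 arrays, at least 23.1-fold lower. SPOCK1, a matrix proteoglycan, was at least 10.2-fold lower, and ALDH2, the mitochondrial aldehyde dehydrogenase, at least 7.63-fold lower. RIT2, EPYC, GH1 and SCN3B, at vector levels between 2.52 and 3.10, were lower by bounds from at least 4.28-fold to at least 6.39-fold. RAMP1, a receptor activity-modifying protein, was measured in both groups, at 4.80 ± 0.04 on the vector arrays and 2.03 ± 0.10 on the BP1 arrays (SD, n = 2 each), with a difference of -2.77 (SE 0.19). PDE9A, a cyclic GMP phosphodiesterase, S100A2, a calcium-binding protein of basal epithelium, HMOX1, the stress-induced heme oxygenase, and IFI27, an interferon-induced gene, differed by -3.65, -3.23, -2.82 and -2.80, which are lower bounds of the size, since 1 BP1 array of each was at the floor. The adjusted p was again 0.293 for each of the 12.

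Because these genes lay near the floor, bright genes were also ranked by the size of their difference, a choice made after the values were seen. CA12, a carbonic anhydrase induced by estrogen, was 3.71-fold lower on the arrays labelled BP1, at 6.06 ± 0.22 against 7.95 ± 0.47 (SD, n = 2 each). S100A14 was 3.29-fold lower, RTN4, a reticulon of the endoplasmic reticulum, 2.84-fold lower, and ID3, an inhibitor of helix-loop-helix factors, 2.39-fold lower, with SE of 0.22, 0.24 and 0.20 on differences of -1.72, -1.51 and -1.26. TPM1, a tropomyosin, differed by -1.68, and SH3BGRL, BAG3, a co-chaperone, TFRC, the transferrin receptor, LGALS3, a galectin, S100A11, FKBP11 and SEC22B were lower by 2.19-fold to 2.99-fold. Higher on the arrays labelled BP1 were KDELR1, a receptor that returns proteins to the endoplasmic reticulum, by 3.77-fold (SE 1.00 on a difference of 1.91), UBE2S, a ubiquitin-conjugating enzyme of mitotic exit, by 3.64-fold (SE 0.61 on 1.86) and HNRNPF, a splicing factor, by 3.09-fold (SE 0.44 on 1.63). MYB, a transcription factor of luminal cells, was 2.51-fold higher (SE 0.32 on 1.33), and TMX1, MRPS12 and ETHE1 were 2.33-fold, 2.18-fold and 2.18-fold higher with SE of 0.23, 0.23 and 0.22. TPM4, MAT2A, PRPF4, TM7SF2 and IER2 were higher by 2.17-fold to 2.59-fold. Adjusted p-values ran from 0.333 for S100A14 to 0.833 for TM7SF2. Leaving out 1 array shrank the difference of 11 of the 24 bright genes by over 1.5 times. Without vector replicate 1 the differences were 0.81 for KDELR1, 1.15 for UBE2S, 0.77 for PRPF4, 0.34 for TM7SF2, 0.67 for IER2 and -0.53 for SEC22B. Without BP1 replicate 1 they were 0.89 for TPM4, 0.68 for MAT2A, -0.62 for TFRC and -0.57 for FKBP11, and without vector replicate 2 it was -0.67 for S100A11. The lower value of vector replicate 1 stands out for KDELR1 (4.06 against 6.26 on vector replicate 2) and UBE2S (6.21 against 7.63).

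**Figure D2:**
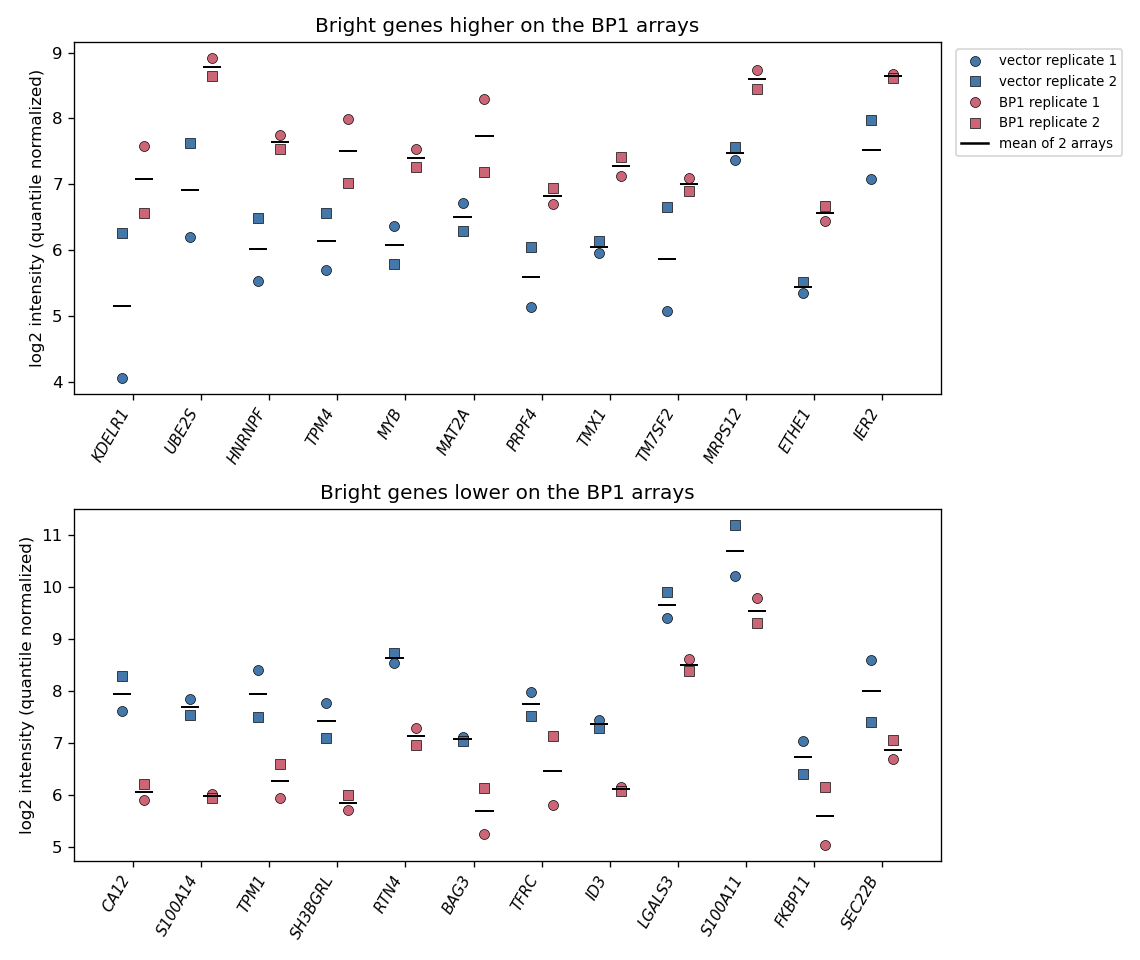
Log2 intensity after quantile normalization (vertical axes, not starting at 0) of 12 bright genes with the largest difference in each direction among those whose arrays stood apart, chosen after the values were seen; circles are replicate 1, squares replicate 2, blue vector and red arrays labelled BP1, with lines at the mean of 2 arrays. S100A14, RTN4 and ID3 show gaps between groups that exceed the spread within them, whereas KDELR1 and TFRC spread widely within a group.

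Of 29 gene lists fixed before the data were examined, none was shifted at an adjusted p under 0.05 in the camera test with a preset correlation of 0.01, nor with an estimated correlation, where the smallest adjusted p was 0.974. The smallest camera adjusted p was 0.249, shared by the hypoxia-induced genes, the homeobox genes and the genes tied to BP1 (mean shift of these 7 against all genes -0.71, median -0.44). The direction that earlier work gave for each of the 7 was not used, so their mean shift speaks neither for nor against that work. Without vector replicate 1 the mean shift of these 7 was -0.17, without BP1 replicate 1 -0.25 and without vector replicate 2 -1.25. Across the lists, 0 members passed over all genes and 8 entries passed adjusted over the list alone. These 8 were PDZK1 and KCNK5 (estrogen-induced), S100A2 (basal), IFI27 (interferon-induced), HOXD4 (homeobox), TGFBR1 (TGF-beta) and, among fibroblast markers, COL1A2 and CDH11. Each of these 8 was at or within 0.06 log2 units of the floor in one group. Arrays set to the floor have no spread between them, which lowers the SE, so these small p-values can rest partly on the floor. Leaving out 1 array moved the mean shift by over 1.5 times for every list except the homeobox and hypoxia-induced genes.

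Hypoxia-induced genes lay lower on the arrays labelled BP1 on average, with 21 of 30 measured members below 0, a mean shift of -0.32 and a camera adjusted p of 0.249. VEGFA, CA12, HK2 (hexokinase, -1.05) and PDK1 (pyruvate dehydrogenase kinase, -1.96, a lower bound of the size with 1 BP1 array at the floor) had the smallest unadjusted p, and 0 of 30 passed. Angiogenic factors had a mean shift of -0.15 over 29 genes (adjusted p = 0.733). After VEGFA, CCN1, a matricellular protein, differed by -1.07, whereas the receptor KDR differed by 1.76 from a vector level of 0.75. Homeobox genes leaned the other way, with 19 of 30 above 0 and a mean shift of 0.34 (camera adjusted p = 0.249), and fry, a test of whether a list's genes move on balance one way, gave an adjusted p of 0.0378. With an estimated correlation the adjusted p of this list in camera was 0.974. HOXD4 was at least 3.93-fold higher and DLX6 at least 1.98-fold higher, PITX1 differed by 1.72 and HOXC10 by 2.05, all from mean vector levels of at most 1.09. The mean level of the list was 2.43.

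Estrogen-induced genes were mixed, with 14 of 33 above 0, 19 below, a mean shift of -0.17 (-0.03 without vector replicate 2) and an adjusted p of 0.873. PDZK1, KCNK5 (a potassium channel, at least 8.61-fold lower) and CA12 were lower and MYB was higher. Luminal epithelial genes had a mean shift of -0.24 over 26 genes (adjusted p = 0.604), or -0.03 without vector replicate 2. Among them TFAP2A, a transcription factor of epithelial cells, differed by -1.97, ANXA9 by -1.92 and SCNN1A, a sodium channel subunit, by -2.21, whereas MYB was higher (1.33). Basal and myoepithelial genes had a mean shift of -0.20 over 21 genes (adjusted p = 0.733), with S100A2 and ANXA1 (-1.40) lower and TRIM29 (2.38) and CAV1, caveolin, (1.59) higher. Epithelial junction genes had a mean shift of -0.08 over 23 genes (adjusted p = 0.916). PERP, a desmosomal protein, differed by 1.06 and CTNNA1, alpha-catenin, by 0.80, whereas DSC2, a desmocollin, differed by -2.64 and OCLN, occludin, by -0.70.

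Mesenchymal genes had a mean shift of 0.28 over 24 genes, 16 of them above 0 (adjusted p = 0.346), at a mean level of 1.88. CDH11, a mesenchymal cadherin, was at least 4.98-fold higher, and S100A4, PDGFRB and COL5A1 differed by 1.63, 1.23 and 1.26. Matrix proteases and invasion genes had a mean shift of 0.02 over 37 genes (adjusted p = 0.938), with TIMP3, a protease inhibitor, at 1.14 and MMP3, a stromelysin, at -1.52. TGF-beta and BMP pathway genes had a mean shift of -0.19 over 39 genes (adjusted p = 0.733), or -0.01 without vector replicate 2. BMP6 (-1.79), BMP2 (-1.49) and ID3 were lower, and the receptor TGFBR1 was at least 5.64-fold higher. Growth factor receptors and ligands had a mean shift of 0.27 over 38 genes (adjusted p = 0.733), with INSR, the insulin receptor, at -1.31, IGF2R at -0.66 (SE 0.19) and FGF12 at 1.67 (1.09 without vector replicate 2).

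Proliferation genes had a mean shift of 0.12 over 50 genes, 31 of them above 0 (adjusted p = 0.508). The mitotic kinesins KIF20A and KIF2C differed by 0.97 and 1.48, and TYMS, thymidylate synthase, and POLA1, a replicative polymerase subunit, by -0.87 and -1.15. The p53 target genes had a mean shift of 0.00 over 25 genes (adjusted p = 0.991), with the death receptor TNFRSF10B at -1.34 and RPS27L at -0.77. The polymerase POLH was at least 7.33-fold higher by the mean, with log2 differences from 2.32 to 3.42 without 1 array. Anti-apoptotic genes had a mean shift of -0.24 over 20 genes (adjusted p = 0.346), led by PEA15 (-1.86), BAG3 and MCL1 (-0.60). Pro-apoptotic genes had a mean shift of -0.03 over 32 genes (adjusted p = 0.873), with PMAIP1 at -1.03, DAPK1 at -1.45 and BAD at 0.77 (0.51 without vector replicate 1). DNA repair genes had a mean shift of -0.02 over 43 genes (adjusted p = 0.991), with the smallest unadjusted p at XPA, an excision repair factor, which differed by -0.92.

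Interferon-induced genes had a mean shift of -0.21 over 34 genes, 20 of them below 0 (adjusted p = 0.508). The mean was -0.02 without BP1 replicate 1 and -0.05 without vector replicate 1. The arrays stood apart by at least 1.5-fold in 6 higher and 10 lower genes. After IFI27, the smallest unadjusted p were those of IFITM2, IFITM3 and IRF9 at -0.89, -0.97 and -0.67, the IFITM pair at vector levels of 8.78 and 9.49. Antigen presentation genes had a mean shift of 0.15 over 24 genes (adjusted p = 0.733), with the class II gene HLA-DRA at least 3.72-fold higher. NF-kappaB target genes had a mean shift of -0.08 over 26 genes (adjusted p = 0.938). Among them LCN2, lipocalin, differed by 2.51 and the chemokine CXCL3 was at least 3.57-fold lower. The CXCL3 difference, a lower bound of the size, was -1.15 without vector replicate 1 and -2.52 without vector replicate 2. Unfolded protein response genes had a mean shift of 0.01 over 18 genes (adjusted p = 0.873), with ATF3, a stress transcription factor, at -1.21, XBP1 at -0.51 and ERN1 at 1.58 (0.69 without vector replicate 2). Heat shock genes had a mean of -0.19 (-0.02 without BP1 replicate 1) and a median of 0.18 over 20 genes (adjusted p = 0.873), with HSPB8 at -1.92 and HSPA9 at 0.52. Cholesterol synthesis genes had a mean shift of -0.02 over 19 genes (adjusted p = 0.765), with FDPS at -0.72. Fatty acid synthesis genes had a mean shift of 0.27 over 13 genes (adjusted p = 0.733), with ACACB at least 6.41-fold higher by the mean. Without 1 array the log2 difference of ACACB ranged from 2.00 to 3.36. Ribosomal protein genes, at a mean level of 11.3, had a mean shift of 0.03 with an SD over 34 genes of 0.23 (adjusted p = 0.873). The globin list, which also holds other erythroid genes such as EPB42 and GATA1, had a mean shift of -0.12 over 9 genes (adjusted p = 0.888). Mean, median and test did not share a sign for the matrix protease, heat shock, ribosomal protein, fibroblast, p53 and unfolded protein response lists. With arrays centred on their medians the means of the DNA repair, cholesterol synthesis and endothelial lists turned sign.

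**Figure D3:**
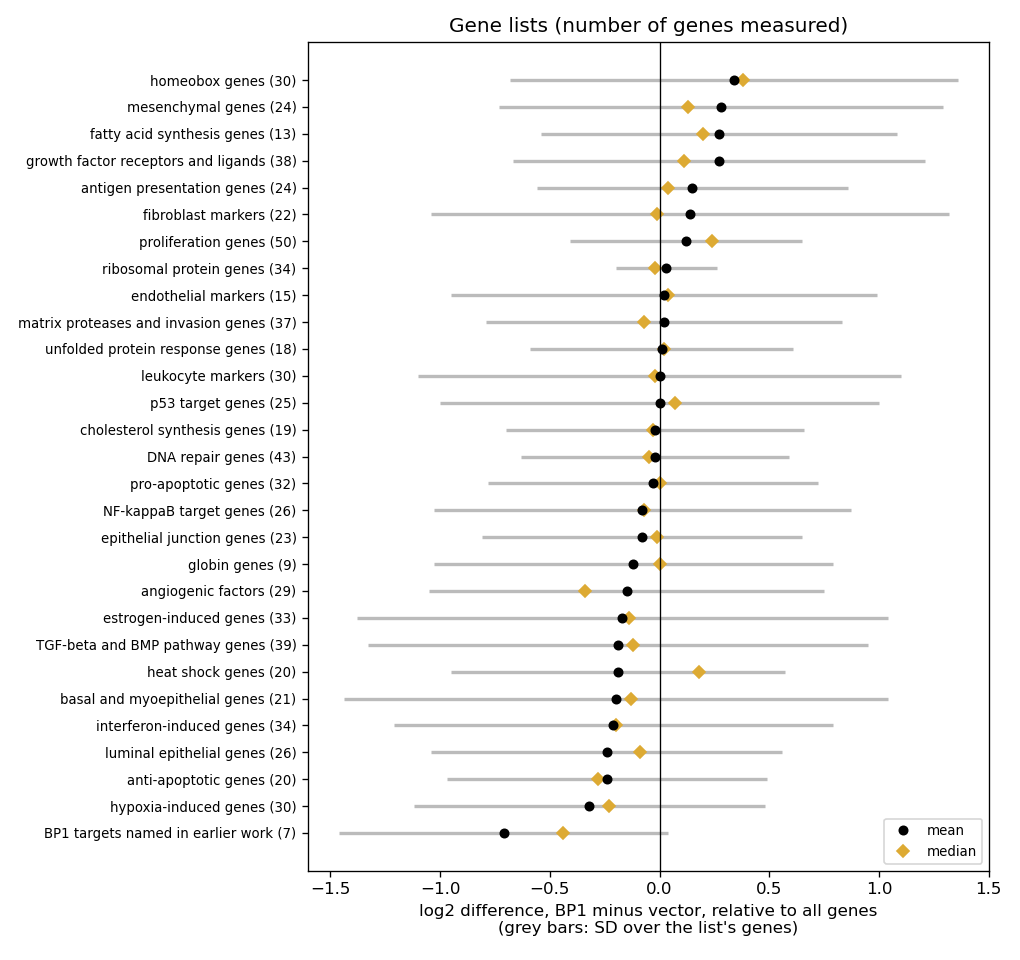
Mean (black circles) and median (yellow diamonds) log2 difference, BP1 minus vector relative to all genes (horizontal axis), of 29 gene lists with the number of genes measured in each; grey bars are the SD over the genes of the list. Means run from -0.71 for the genes tied to BP1 in earlier work to 0.34 for homeobox genes, and every bar crosses 0.

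No list of markers of cell types other than epithelial cells was shifted. Leukocyte markers averaged 1.70 over 30 genes with a mean shift of 0.00 (adjusted p = 0.916). CORO1A, an actin regulator of leukocytes, differed by 3.12, with 4.49 and 5.29 on the arrays labelled BP1, and CD14 was at least 2.77-fold lower. Fibroblast markers averaged 1.44 over 22 genes with a mean shift of 0.14 (adjusted p = 0.733), where COL1A2, a fibrillar collagen, was at least 5.68-fold lower and CDH11 higher. Endothelial markers averaged 1.48 over 15 genes with a mean shift of 0.02 (adjusted p = 0.991), and after KDR the next was EMCN at -1.22.

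The control transcripts differed between arrays in their 5′ to 3′ ratio, a sign of RNA quality. For ACTB, beta-actin, the 5′ over 3′ ratio was 0.15 on vector replicate 1, 0.602 on vector replicate 2, 1.05 on BP1 replicate 1 and 0.98 on BP1 replicate 2. For GAPDH it ran from 0.709 on vector replicate 2 to 0.948 on BP1 replicate 2, with 0.795 on vector replicate 1. For STAT1 it was 0.136 and 0.0845 on the vector arrays and 0.388 and 0.327 on the arrays labelled BP1. In all 3 transcripts both BP1 arrays had a higher ratio than both vector arrays. Differences between the groups can therefore not be told apart from a difference in RNA quality. The ribosomal RNA controls grouped the arrays another way: the 18S control read 242 on vector replicate 1 and 394 on BP1 replicate 2, but 29.6 and 61.4 on the others. In an exact permutation test 2 arrays against 2 cannot give a two-sided p below 0.333.

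**Figure D4:**
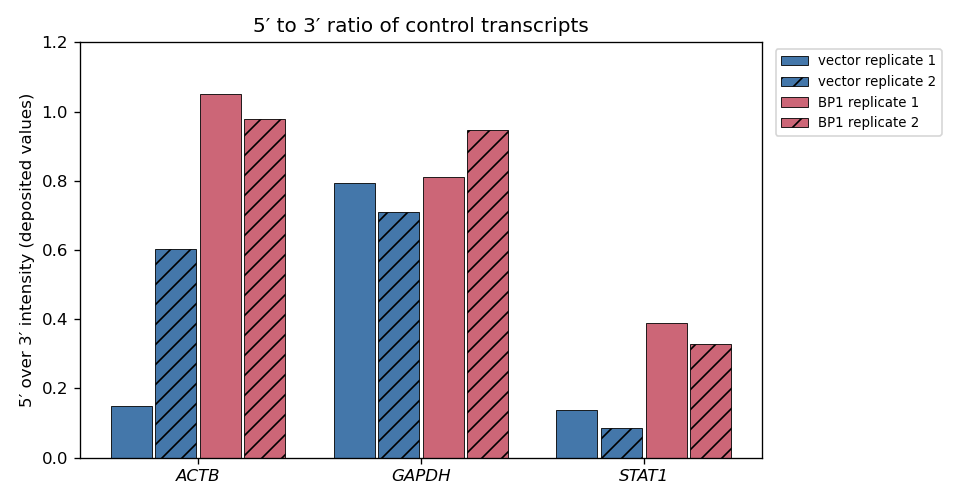
Ratio of the 5′ to the 3′ control probe set of ACTB, GAPDH and STAT1 (vertical axis, deposited intensities) on each of the 4 arrays, blue for vector and red for arrays labelled BP1, hatched for replicate 2. The ACTB bar of vector replicate 1 stands at 0.15, against 0.602 to 1.05 on the other arrays.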

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

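Both tests of the low ACTB signal were chosen after values of the arrays had been seen. Of 47 control probe sets outside the main comparison, 2 lay higher on both arrays labelled BP1 than on both vector arrays after median centring, where chance gives 7.83. One of them, the middle probe set of the bacterial thr control, exceeded the higher vector array by 0.3 log2 units on the lower BP1 array.

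The other was the 5′ ACTB control, which exceeded the higher vector array by 0.22 log2 units and lay at 4.83 on vector replicate 1 against 7.55 to 7.85 on the other arrays. Degraded RNA on vector replicate 1 is a candidate explanation. It would lower the 5′ end of GAPDH too, but the GAPDH ratio of vector replicate 1 was 1.12 times the lowest of the other arrays, and the STAT1 ratio was 0.136 against 0.0845 on vector replicate 2. The lowest GAPDH and STAT1 ratios were those of vector replicate 2. For ACTB, GAPDH and STAT1 both vector arrays lay below both BP1 arrays. Lower RNA quality of the vector group can therefore not be told apart from a difference between the groups. With single arrays and no measure of their spread, degradation of vector replicate 1 stays open. How far this array makes the differences of the named genes stays open: without it the median share left over 48 genes was 0.964, but these genes were chosen for arrays that stood apart, and leaving out each of the others gave 0.977 to 1.04. A difference of ACTB transcripts between clones was not tested.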

How the results depend on the processing

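No normalization, filter, variance model, threshold or left-out array gave a probe set at an adjusted p under 0.05, nor at the threshold of 0.10 in the fit reported here. This includes the fits without vector replicate 1 and without BP1 replicate 2, the arrays doubted for ACTB and DLX4. The count at an unadjusted p under 0.05 moved from 667 to 439 (31 under 0.01, from 200) with the replicate block, to 548 (61 under 0.01) with the crossed replicate block, and to between 784 and 999 without 1 array. No paired effect is claimed, since 2 shared numbers do not show pairing. The replicate differences of the groups correlated at -0.047 over all probe sets and -0.429 over bright ones, which could mean crossed numbers. Gene density went with them too. Among bright genes the difference of replicate 1 minus 2 correlated with gene density at -0.353 for vector and 0.197 for BP1. The cause was not tested. Both the replicate block and the crossed block gave 0 calls. Without normalization the count was 934, 801 of them higher (85.8%, against 51% in the fit reported here), and with median centring 43.3% of 520 were higher. With the filter at a mean level of 6, 126 of 1390 were under 0.05 and 22 under 0.01, and with the trend added 135 and 31. That last fit, chosen after seeing the data, called 34%, 77.4% and 89.2% of simulated changes of 1, 2 and 3 log2 units. The simulation changed 200 bright probe sets at once. On the arrays, where the number changed is not known, the smallest adjusted p of this fit was 0.235. The number of lists past the threshold went from 0 to 1 with fry (homeobox genes, mean shift 0.34, adjusted p = 0.0378) and to 1 without normalization (ribosomal protein genes, 0.07, adjusted p = 0.0393); the cause was not tested. DLX4 turned to 0.02 without normalization, taken relative to the median shift of all probe sets (0.52), and ranged from -1.22 (without BP1 replicate 1) to 1.16 (without BP1 replicate 2). Directions of lists that turned were, with median centring and equally without normalization, DNA repair 0.01, cholesterol synthesis 0.02 and endothelial -0.06; with the filter at 6, luminal 0.09 and junction genes 0.22; and without the dimmest probe sets (6559 kept), matrix proteases -0.02, NF-kappaB 0.05 and fibroblast -0.28. Without 1 array, ranges that cross 0 were ESR1 -0.70 to 0.33, BRCA1 -1.16 to 0.23, HBE1 -1.82 to 0.15, GATA1 -0.57 to 2.62, BCL2 -1.11 to 1.12, p53 targets -0.10 to 0.11, leukocyte markers -0.16 to 0.15, matrix proteases -0.33 to 0.38, DNA repair -0.14 to 0.11, globin -0.68 to 0.43, junction -0.26 to 0.10, unfolded protein response -0.07 to 0.08, cholesterol synthesis -0.19 to 0.15, ribosomal -0.03 to 0.08, endothelial -0.22 to 0.25, anti-apoptotic -0.49 to 0.01, antigen presentation -0.04 to 0.34, NF-kappaB -0.26 to 0.11, proliferation -0.08 to 0.32 and pro-apoptotic -0.21 to 0.15. Without 1 array 42 of 147 named genes moved by over 1.5 times. Other ranges of that size among lists and the genes tied to BP1 were HBB -3.69 to -0.39, PGR -0.81 to -0.06, TFF1 -0.60 to -0.27, BP1 targets -1.25 to -0.17, estrogen-induced -0.32 to -0.03, luminal -0.45 to -0.03, heat shock -0.36 to -0.02, interferon-induced -0.41 to -0.02, TGF-beta -0.37 to -0.01, fatty acid 0.10 to 0.45, fibroblast 0.04 to 0.23, growth factor receptors 0.08 to 0.46, mesenchymal 0.15 to 0.41, angiogenic -0.20 to -0.09 and basal -0.28 to -0.12, whereas homeobox genes stayed within 0.31 to 0.37 and hypoxia-induced genes within -0.36 to -0.29. EPB42, at the floor on every array except vector replicate 1, went from -0.33, a lower bound of the size, to 0 without that array. Named genes other than these and DLX4 kept their direction in every setting that kept their probe set. Leaving out an array kept the normalization over all 4, and the lone array of a group was assumed to vary like the other group. Robust eBayes was run for genes only.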

Other observations

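The tests of swapped or wrong labels, of copy number changes of single clones, of the S100 family and of other splits were chosen after the values were seen, and so was the restriction of the neighbour tests to bright genes, after minimum levels of 0, 4 and 6 had been looked at; the other tests here were written before their results. Genes of the S100 family, small calcium-binding proteins of epithelia, lay lower on the arrays labelled BP1 in 12 of 15 measured members, with a mean difference of -0.75 (12 of 15 and -0.89 with arrays centred on their medians). S100A14, S100A11 and S100A10 differed by -1.72, -1.15 and -0.88, and S100A8 and S100A9 by -0.82 and -0.68, whereas S100A13 and S100A4 differed by 0.45 and 1.63. The camera test over all 15 gave an unadjusted p of 0.00499, but 0.0955 with an estimated correlation, so a chance selection of the family stays open.

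Most of these S100 genes are neighbours in the genome, and neighbouring genes tended to differ together. Among 1202 bright genes ordered along the chromosomes of GRCh38.p14, the log2 differences of adjacent genes correlated at 0.28 across genes, above all 1000 random gene orders (p = 0.001, the smallest they can give). Over all 7711 placed genes the correlation was 0.023 (p = 0.03), and without vector replicate 1 it was -0.005 (p = 0.7). Runs of 7 neighbours were taken over the 3052 genes with a mean level of at least 4, which leaves out dimmer members such as S100A4 and S100A2. Their highest mean was that of RPS9, TNNT1, HSPBP1, UBE2S, ZNF580, U2AF2 and ZNF274, at 1.08, all above 0, with a permutation p of 0.005 against the maximum of 1000 random orders. Their lowest was that of S100A10, S100A11, SPRR1B, S100A9, S100A8, S100A6 and S100A14, at -0.95, all below 0, with a permutation p of 0.014. Without vector replicate 1 the RPS9 run had a mean of 0.81 and the S100 run of -0.93. Vector replicate 1 minus 2 was -0.54 in the RPS9 run and 0.04 in the S100 run. The runs were not tested after a regression on gene density.

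The gene density of a region, which goes with base composition, is a technical candidate explanation. It was argued against as the whole cause: after regression on gene density and gene length the bright genes kept a share of 0.923 of their correlation, at 0.259, whereas the correlation of the difference between the vector replicates went from 0.141 to 0.023. The difference between groups itself correlated with gene density at 0.177 among bright genes. Without vector replicate 1 that value was -0.068, without vector replicate 2 0.312, without BP1 replicate 1 0.071 and without BP1 replicate 2 0.231. Vector replicate 1 alone was argued against for bright genes, whose correlation without it was 0.191, but not over all genes. Copy number changes of single clones should show between replicates too, where the correlation was 0.028 for BP1 and 0.141 for vector, lower than between groups by at least 0.139 (95% interval over resampled chromosomes from 0 to 0.251) and by at least 0.235 after the regression (0.111 to 0.323). Such changes stay open, as the first interval reaches 0, and so may changes shared by the clones of a group or shared regulation of neighbours; the base composition of the probes was not tested.

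That DLX4 was not higher on the array labelled BP1 replicate 2 may be noise of a dim probe set. The 2.38 log2 units between the BP1 arrays lay at percentile 91.5 of replicate differences among 1021 probe sets of like level. A wrong label of that array alone stays open. Over bright probe sets it correlated better with the other BP1 array than with either vector array, by 0.022. Over all probe sets it correlated less well with the other BP1 array than with vector replicate 2, with a difference of -0.014. The vector arrays did not group over bright probe sets, where they correlated at 0.908 and the BP1 arrays at 0.947. Vector replicate 2 correlated at 0.939 with BP1 replicate 1 and at 0.925 with BP1 replicate 2. Vector replicate 1 correlated at 0.922 with BP1 replicate 2, and only its correlation with BP1 replicate 1 (0.876) was below 0.908. The test of a swap asked for a vector value of at least that of BP1 replicate 1. The highest was -0.85 log2 units away, within the noise of such probe sets. A swap would not need such a value, only both true BP1 arrays above both true vector arrays. Vector replicate 2 (3.54) and BP1 replicate 1 (4.39) did lie above vector replicate 1 (2.93) and BP1 replicate 2 (2.02). A swap of vector replicate 2 with BP1 replicate 2 therefore stays open. Whether the probe set reads the transgene was not tested.

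Another split of the 4 arrays gave about as much as the real one. With 3 possible splits no share under 0.05 can be reached. As the 1 split of 3 with at least that many, BP1 against vector gave 667 probe sets at an unadjusted p under 0.05, and the highest of the others gave 646. That other split, vector replicate 2 and BP1 replicate 1 against the rest, gave more than the real one at an unadjusted p under 0.01 (205 against 200). It parted more bright probe sets (562 against 530) and more of them by at least 2-fold (60 against 57), and it is the split of the 18S control. The DLX4 values part the arrays the same way, with 3.54 and 4.39 against 2.93 and 2.02. Swapped labels of vector replicate 2 and BP1 replicate 2 would give this grouping. Other values part the arrays as labelled: the 5′ to 3′ ratios of ACTB, GAPDH and STAT1 and the share of probe sets at the lowest value. The highest correlation over bright probe sets, 0.947, was that of the 2 BP1 arrays. Over all probe sets it was 0.905, between vector replicate 2 and BP1 replicate 2, which differ in group with or without the swap. Such a swap stays open. Probe sets at the floor in both arrays of one side and at least at 3 in both of the other numbered 16 in the real split, 1.45 times the mean of 11 in the other splits (95% interval from 0.714 to 2.90). The tolerance for values at the floor, set after the values were seen, brought this ratio from just above to below 1.5, the bound set beforehand, and the interval spans that bound either way. Noise of dim probe sets therefore could not be told apart from a difference between groups for genes such as TEX14 and PDZK1.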
